A study of Mus musculus with 18 samples.

How the data were processed

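RNA was sequenced from 2 mouse embryonic tissues of the ICR strain. The first sample was made of GFP-positive cells sorted by flow cytometry from trypsin-dissociated E12.5 neural tubes, and the second was whole E15.5 pancreas. Per the labels, each of the 2 samples named 2 libraries, but the deposited table held 1 value per gene and tissue, so each column was read as the authors' pooled value for that tissue. No replicate values were used, and no SD, p-value or replicate check is given.

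The values were FPKM, fragments per kilobase of transcript scaled to the total of mapped fragments, as the authors deposited them. Per the submitters' processing notes, the tools named were CASAVA, TopHat, TopHat2 version 2.0.4 and Cuffdiff version 2.0.2, and the genome build was mm9. The notes used here give no role or order for these tools, and the gene annotation and any filter are not given in the sources used here. Per the labels' protocols, RNA was extracted with a column kit from the sorted cells and with Trizol from the pancreas. Per the same protocols, an Illumina mRNA-seq preparation was named for neural tube and pancreas and a TruSeq mRNA preparation for pancreas. Tissue, stage, sorting, extraction and possibly library preparation therefore all differed between the same 2 samples. A per-kilobase value depends on the transcript length assumed, and a value scaled to the library total depends on what the most abundant genes take.

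The table listed 23228 gene symbols, of which 0 appeared more than once. Both value columns were used. For 21662 symbols (93.3%) a single gene of that name was found in GENCODE M1 on NCBIM37, the same build as mm9, and coordinates come from there. The remaining 16 of the 18 samples of the series, made up of 11 chromatin immunoprecipitation, 2 input and 3 open-chromatin (FAIRE) samples, are not analysed here.

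For each gene the difference was log2(FPKM + 1) in neural tube minus log2(FPKM + 1) in pancreas, a scale that understates the difference of low genes. A gene was called higher in one sample when it differed by at least 4 times on that scale (2 in log2) with at least 5 FPKM in the higher sample. It was called similar when both values were at least 5 FPKM and lay within 2 times of each other. These are rules of size and not tests. For each gene list, members at 1 FPKM or more in either sample gave the median difference, and its percentile was taken among 10000 random lists of the same size matched on mean expression in 20 bins. That percentile describes these samples only. Exact zeros are reported as listed at 0, because Eif3j, a translation initiation factor subunit, was itself listed at 0 in the neural tube sample and at 47.1 FPKM in pancreas.

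Before the data were examined, 31 gene lists, the thresholds, the alternatives and the rule for naming genes were fixed. The rule named every member of the PTF1 list, the 2 largest and 2 smallest differences of each list among members at 5 FPKM or more, the 10 largest differences in each direction and the 10 highest values in each sample. Small RNA genes and models without an approved-looking symbol were left out of those last groups. It also named Foxa2, the Sox, Pax, Hox and POU or LIM members past the rule of size, and the 5 listed transcription factors with the highest mean among similar genes. Which genes counted as transcription factors for that last part was completed with further symbols after the values were seen. A further 8 lists, the correction for transcript length and GC content, and the tests of explanations were also chosen after the values were seen, as were genes said to be so in the text. Some genes that the rule names are not reported here.

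Depth was not stated as counts. Among genes with 1 annotated transcript, the most frequent low step of FPKM times length put 1 fragment on a 1 kb transcript at about 0.0437 FPKM in neural tube (983 genes) and 0.0240 FPKM in pancreas (1531 genes). A 3-fragment floor at 1 kb corresponds to 0.131 and 0.0720 FPKM, and the ratio of the steps to a depth 1.82 times greater in pancreas. At 5 FPKM a 1 kb transcript would hold about 114.5 and 208.4 fragments. These are approximate, because the lengths were those of GENCODE and many values were not whole multiples of a step, so no interval per gene is given.

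The alternatives were pseudocounts of 0.1 and 5 FPKM, no filter and a filter of 10 FPKM, 5 rescalings of the samples, small RNA genes left out, thresholds of 2 and 8 times, and similarity within 1.5 times. The rescalings were to the median ratio, to the upper quartile, to the housekeeping list, to equal totals over all genes, and to equal totals without the acinar enzyme list, small RNA genes and the 50 highest genes of each sample. The length and GC correction removed the median difference in 20 bins of each property over 3 rounds. The measure was tested on simulated data, in which 23228 genes started from the geometric mean of their 2 values with independent noise added. Changed genes were drawn from those at 10 FPKM or more. With 100 genes changed by 8 times, 100% were called, and with 100 changed by 3 times, below the rule, 13% were called. Of 23028 unchanged genes 0% were called, and of 300 random lists 4.67% fell outside the central 95%. The noise was set by hand, with no replicates to set it from, and was far smaller than the rule of size. The 0% therefore follows from that setting and is not a rate of false calls in these data. The 100% at 8 times follows from it too. The 4.67% follows from drawing lists at random with noise independent between genes. It does not cover lists of genes that vary together. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.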

Results

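Ptf1a is a basic helix-loop-helix transcription factor needed both for pancreas formation and for the inhibitory neurons of the dorsal neural tube. Most samples of the series are of chromatin, and only the RNA samples of these 2 tissues are used here. Expression was measured by RNA sequencing in 1 pooled sample of each tissue. The neural tube cells were GFP-positive cells sorted at E12.5 from embryos carrying a transgene in which a 2.3 kb autoregulatory enhancer of Ptf1a drives GFP. Per the labels this enhancer lies on chromosome 2 at 19351717 to 19354014 (mm9), 13275 bases upstream of the annotated Ptf1a gene. The other sample was whole E15.5 pancreas, which was not sorted. The depth inferred from the lowest steps of the values was 1.82 times greater in pancreas. No sample was replicated in the values used, so each difference describes these 2 samples without a replicate check.

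Digestive enzyme, duct and epithelial genes were high in the pancreas sample, and inhibitory interneuron, neural progenitor, neuronal and Hox genes were high in the neural tube sample. By the rule of size 1106 genes were higher in neural tube and 1278 were higher in pancreas, among 10744 genes at 5 FPKM or more in either. Of these, 469 were below 1 FPKM in pancreas and 694 were below 1 FPKM in neural tube, respectively. Another 4813 genes were similar, 68.4% of the 7037 genes at 5 FPKM or more in both. Across the 14303 genes at 1 FPKM or more in either sample, Pearson's r of log2(FPKM + 1) was 0.59 and Spearman's rho 0.56. These correlations are across genes, which are not independent replicates.

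The 10 largest differences toward pancreas were led by Ctrb1, which encodes chymotrypsinogen B, at 0.0688 FPKM in neural tube and 21063 in pancreas. Toward neural tube, the zinc finger gene Zic1 stood at 213 FPKM against 0.0140 in pancreas, Hoxb9 at 284 against 0.406, and Robo3, an axon guidance receptor, at 201 against 0.0260. The neuronal repressor Scrt2 was at 140.1 against 0.0343 FPKM, and Tagln3 at 236 against 1.42. The calls were 46.4% toward neural tube, and 65.0% with the samples rescaled to equal totals or 58.9% with housekeeping centring. They were 42.9% with upper quartile scaling and 39.6% with a correction for transcript length and GC content. The median difference of all genes at 1 FPKM in both, 0.02 as deposited, moved to 0.60 with equal totals, to 0.35 with housekeeping centring and to 0.32 without the most abundant genes.

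**Figure D1:**
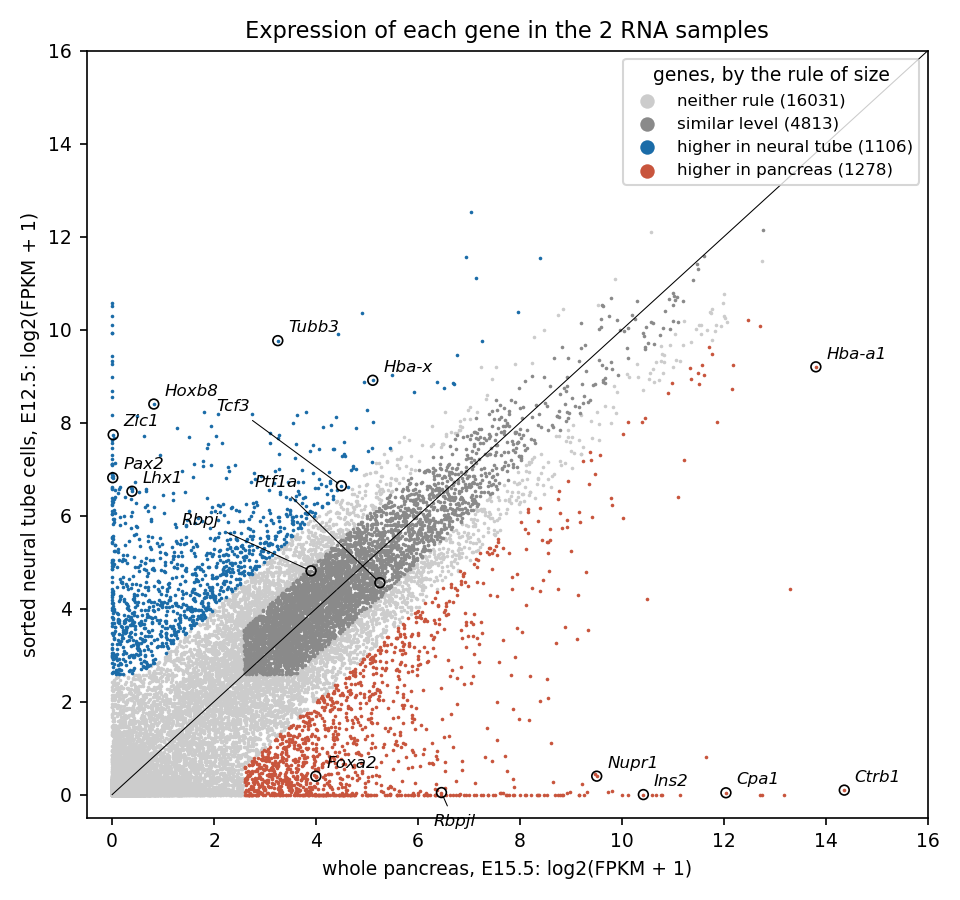
Each point is a gene, with log2(FPKM + 1) in whole E15.5 pancreas on the horizontal axis and in sorted E12.5 neural tube cells on the vertical axis, coloured by the rule of size; the line marks equal values. The 1106 genes higher in neural tube and the 1278 higher in pancreas lie away from the line, and Ptf1a lies near it.

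Ptf1a itself was expressed in both samples, while one of its partners was seen almost only in pancreas. Ptf1a (chromosome 2, 19367290 to 19369128) had 22.5 FPKM in neural tube and 37.1 in pancreas, a difference of -0.69 in log2 that counts as similar within 2 times but not within 1.5 times. In the sorted sample, cells had been selected by an enhancer of this gene, whereas pancreas was whole tissue, so these levels are per sample and not per Ptf1a-expressing cell. Rbpj, the Notch effector that joins Ptf1a and an E protein in the PTF1 complex, was also similar at 27.1 and 14.0 FPKM. Its difference of 0.91 ranged from 0.76 to 1.54 over the alternatives, and the similar call was lost with equal totals, housekeeping centring, rescaling without the most abundant genes, the length and GC correction and similarity within 1.5 times. Rbpjl, its paralog in the acinar form of the complex (chromosome 2, 164228641 to 164240948), was at 0.0306 FPKM in neural tube and 87.1 in pancreas. The neural tube value is below the 3-fragment level of a 1 kb transcript.

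Of the E proteins, which pair with Ptf1a, Tcf3 was higher in neural tube by the rule of size. Tcf3 had 98.8 FPKM against 21.6, Tcf12 71.7 against 25.4 and Tcf4 40.8 against 11.6. Over the alternatives the difference ranged from 1.00 to 2.78 for Tcf3, from 1.47 to 2.38 for Tcf4 and from 1.34 to 2.09 for Tcf12, so each of these calls changed under some setting. For the 6 genes of the list, the median difference was 1.19 and the mean -0.14, opposite in sign with Rbpjl at -6.42, and the median lay at percentile 97.99 of random lists.

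**Figure D2:**
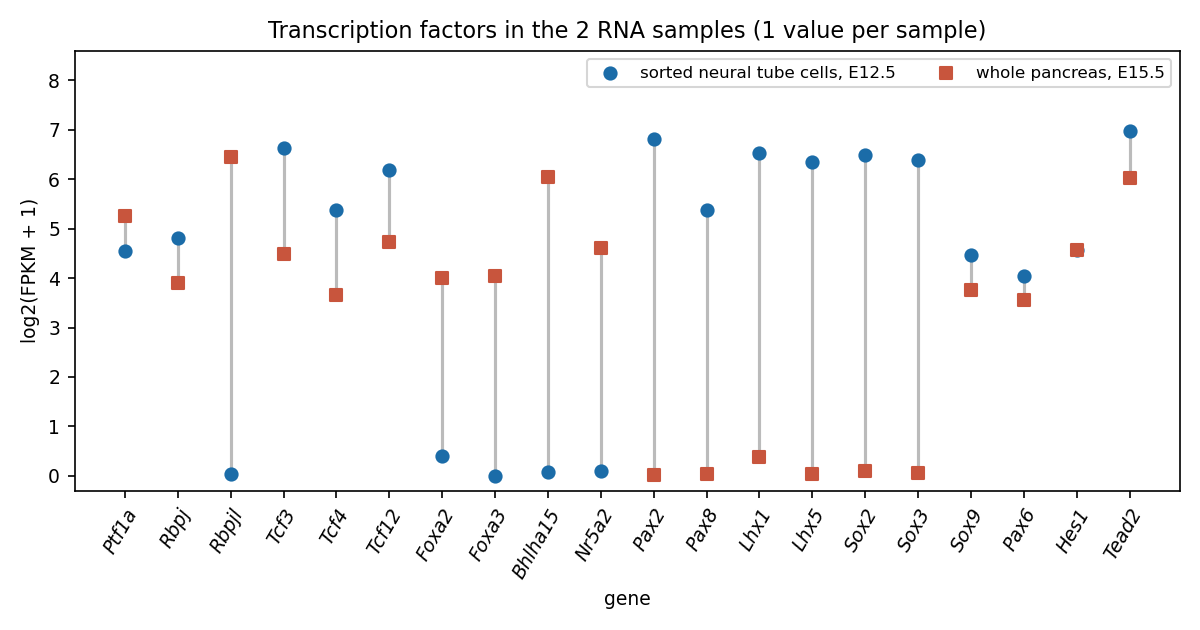
For each transcription factor, the circle is log2(FPKM + 1) in sorted E12.5 neural tube cells and the square is that in whole E15.5 pancreas, with 1 value per sample and no error. Ptf1a and Hes1 have close values, Rbpjl, Foxa2 and Bhlha15 are high in pancreas, and Pax2, Lhx1 and Sox2 are high in neural tube.

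Most acinar genes were higher in pancreas. Of the 30 acinar enzymes and secreted proteins, 24 were higher in pancreas and 0 in neural tube, with a median difference of -8.46 (percentile 0). The list took 7.35% of all FPKM in pancreas and 0.000659% in neural tube. The carboxypeptidase gene Cpa1 was at 4213 FPKM in pancreas against 0.0275 in neural tube. Clps, the colipase that assists pancreatic lipase, reached 6693 FPKM and was listed at 0 in neural tube, as were the trypsin inhibitor Spink3 at 1105 and Serpina6 at 1629. Cela3b, an elastase, was at 893 against 0.0545. Amy2b, an amylase gene that the GENCODE annotation used here types as a pseudogene, was at 9313 against 0.000890 FPKM. Its value is uncertain because amylase copies are nearly identical. The smallest differences among members at 5 FPKM or more were those of Ctrc at 8.30 FPKM and Zg16 at 22.2 in pancreas, both listed at 0 in neural tube. Members below that level differed by less, such as Ctrl at 3.16 in pancreas against 1.37. The lipase gene Pnlip was at 1.03 in pancreas and listed at 0 in neural tube.

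Genes of the secretory pathway were also higher in pancreas, 15 of 20 by the rule, with a median of -2.84 (percentile 0). The stress-responsive gene Nupr1 had 726 FPKM against 0.316, and the disulfide isomerase Pdia2 had 197 against 0.0249. The chaperones Calr, at 746 against 248, and Canx, at 187 against 59.3, differed by less than the rule.

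Transcription factors of the pancreatic epithelium were higher in pancreas for 12 of 24 genes and higher in neural tube for 0 (median -3.04, percentile 0). Bhlha15, an acinar maturation factor also called Mist1, was at 64.9 FPKM against 0.0611 and Nr5a2 at 23.3 against 0.0738. Foxa2, a forkhead factor of endoderm and one of the proteins studied by chromatin immunoprecipitation in the series, was at 14.9 against 0.315, and Foxa3 was at 15.45 and listed at 0 in neural tube. Named after their values were seen, Gata4 was at 26.9 against 0.237 and Pdx1 at 13.9 against 0.0293. Tead2, a Hippo pathway factor, was similar at 64.2 in pancreas and 125.5 in neural tube, and Prox1 was at 5.22 against 12.8.

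Most endocrine and duct markers were higher in pancreas. Of 25 endocrine markers 15 were higher in pancreas and 1, Mafa at 8.93 FPKM against 0.513, was higher in neural tube (list median -2.48, percentile 0). Ins2, an insulin gene, was at 1370 FPKM and listed at 0 in neural tube, and Gcg, which encodes glucagon, was at 712 against 0.354. The zinc finger gene Insm1 was at 24.6 in neural tube and 6.19 in pancreas. Somatostatin, Sst, chosen after its values were seen, was at 145 FPKM in neural tube and 41.0 in pancreas. Of 16 duct and epithelial markers 12 were higher in pancreas (median -4.64, percentile 0), with Spp1 at 398 against 0.203 and Krt18 at 290 against 2.04 FPKM. Car2 and Tjp3 were lower in neural tube by less than the rule, with differences of -1.98 and -1.65.

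The sorted neural tube cells carried the inhibitory dorsal interneuron genes. Of 26 such genes 21 were higher in neural tube and 0 in pancreas (median 4.92, percentile 100). Pax2, a marker of inhibitory neurons, was at 112 FPKM against 0.00811, and Tfap2b at 92.4 against 0.0415. Named after their values were seen, Lbx1 was at 73.7 and listed at 0 in pancreas, Slc32a1, the vesicular inhibitory amino acid transporter, was at 46.1 against 0.0176, and Gad1, which makes GABA, was at 28.0 against 0.539. The smallest differences were those of Ptf1a and of Nphs1, which encodes nephrin and was similar at 14.0 and 7.21. Its genomic neighbour Kirrel2, also named after seeing its values, was at 47.4 in neural tube and 18.9 in pancreas.

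Some excitatory dorsal genes were also higher in neural tube. Of 21 genes 6 were higher in neural tube and 1 in pancreas (median 1.76, percentile 100). Olig3, a dorsal progenitor factor, was at 24.6 FPKM and Tlx3, a selector of glutamatergic neurons, at 18.2, both listed at 0 in pancreas. Lmx1b was at 14.9 against 0.241. Foxp2 was at 8.18 against 1.54. Isl1, expressed in endocrine cells as well as in neurons, was at 2.67 in neural tube and 16.5 in pancreas. Of 22 ventral neural tube markers only 9 reached 1 FPKM in either sample and 0 were called higher in neural tube. None reached 5 FPKM in neural tube, so none could be called toward it. En1 at 2.83 FPKM against 0.0219, and Olig2 at 2.71 and listed at 0 in pancreas, were higher there below that minimum. The 2 calls of this list were toward pancreas, Foxa2 and Nkx2-2, which are also pancreatic factors. The ventral median of -1.07 (percentile 12.5) turned to 0.14 with rescaling to equal totals, 0.46 without the most abundant genes and 0.15 without a filter.

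Progenitor and neuronal genes were both high in the sorted cells. Of 23 neural progenitor markers 20 were higher in neural tube (median 4.04, percentile 100), and Sox2, a neural stem cell factor, was at 88.8 FPKM against 0.0773. Hes1, a Notch target, was similar at 22.6 and 22.8, and Prom1 was at 13.4 in neural tube against 30.7. All 29 pan-neuronal genes found in the table passed the rule (median 4.00, percentile 100). Tubb3, a neuronal tubulin, was at 869 FPKM against 8.51 and Ina, a neurofilament-related protein, at 208 against 0.552. Gap43 and Nefm had the smallest differences, with Gap43 at 67.1 against 14.2 and Nefm at 22.7 against 3.97.

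Hox, Pax, POU, LIM and Sox genes past the rule were higher in neural tube except Isl1. Of 39 Hox genes 26 were higher in neural tube and 0 in pancreas (median 3.82, percentile 100). Hoxb8 was at 337 FPKM against 0.762, Hoxb6 at 143 against 2.45 and Hoxa5 at 89.8 against 8.78, while Hoxd8 at 8.81 against 2.55 stayed below the rule. Of 9 Pax genes 5 were higher in neural tube (median 3.02, percentile 100), including Pax8 at 40.6 against 0.0333, Pax3 at 29.2 against 0.0123 and Pax7 at 10.05 against 0.0190. Pax6, used in both tissues, was similar at 15.52 and 10.8. Of 27 POU and LIM homeobox genes 10 were higher in neural tube and 1, Isl1, in pancreas (median 3.19, percentile 100). The median is that of the 15 members at 1 FPKM or more in either sample, and at its weakest was 0.51 over the alternatives. Lhx1 and Lhx5, of inhibitory interneurons, were at 91.1 and 80.7 FPKM against 0.309 and 0.0287. Pou3f3 was at 64.3 and listed at 0 in pancreas.

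Of 19 Sox genes 7 were higher in neural tube and 0 in pancreas (median 1.31, percentile 100). Sox3 was at 83.2 against 0.0463, Sox11 at 136 against 2.84 and Sox4 at 171 against 15.7. Sox9, a progenitor factor in both tissues, was similar at 21.2 and 12.6 FPKM, and the endothelial factor Sox18 was at 2.09 against 5.51. Of 44 Fox genes 2 were higher in each sample, with a median of 0.69 for 27 members at 1 FPKM (percentile 99.0, lowest alternative 0.16). Foxp4, at 55.4 against 11.9, and Foxb1, at 5.25 against 0.0155, were those of the neural tube.

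Notch pathway genes that passed the rule were higher in neural tube, and only 1 of 25 cell cycle genes passed it. Of 25 Notch pathway genes 6 were higher in neural tube, 0 in pancreas and 6 similar (median 0.85, percentile 99.5). The effector Hes5 was at 65.2 FPKM against 0.0404 and the ligand Dll3 at 44.5 against 0.441. Dll4, a ligand used in vessels, was at 0.699 against 5.33 and Heyl at 1.30 against 5.37. Of 25 cell cycle genes 14 were similar and 1, the mitotic kinase gene Cdk1 at 14.2 against 66.5, was higher in pancreas. Over all genes at 5 FPKM or more in both samples 68.4% were similar, so similarity is not particular to this list. Bub1 was at 5.50 against 15.6, Mcm2 at 81.4 against 36.4 and E2f1 at 49.2 against 14.0, none of which passed the rule. The cell cycle median of -0.37 (percentile 18.9) turned to 0.24 with rescaling to equal totals. Among the listed transcription factors only, the 5 similar ones with the highest mean were Tead2, Ptf1a, Hes1, Rbpj and Jun. That set was completed after the values were seen and does not cover all transcription factors. Jun was at 19.99 and 15.6 FPKM. Tead2, with a difference of 0.96 that reached 1.58, was no longer similar under the same 3 rescalings that ended the call of Rbpj, nor within 1.5 times.

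Markers of cells other than pancreatic epithelium also separated the sorted cells from the whole tissue. Of 20 mesenchyme markers 13 were higher in pancreas (median -2.98, percentile 0), with the proteoglycan gene Dcn at 175 against 0.660 FPKM and the collagen gene Col6a1 at 90.9 against 0.633. Twist1 was the 1 marker higher in neural tube, at 15.8 against 1.39, and Fn1 was similar at 34.5 in neural tube and 22.3 in pancreas. Of 15 endothelial markers 7 were higher in pancreas (median -1.98, percentile 0), including Pecam1 at 24.3 against 1.39 and Emcn at 12.9 against 1.01, and Cldn5 was similar at 7.73 in pancreas and 5.23 in neural tube. Of 15 immune markers 8 were higher in pancreas (median -2.36, percentile 0). Among them Lyz2, of macrophages, was at 106 FPKM against 0.233, C1qa at 68.7 against 0.977 and Laptm5 at 9.40 against 1.03. Cd68 was at 7.07 against 3.37.

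Red cell genes split by kind. Of 12 erythroid markers 6 were higher in pancreas and 3 in neural tube (median -3.78, percentile 0). The adult globins Hba-a1, at 14315 FPKM against 587, and Hbb-b1, at 1449 against 17.5, were higher in pancreas. Hbb-b2, at 6919 against 0.000915, and Beta-s, at 10121 against 20.5, are near-identical copies whose separate values are uncertain. The embryonic globins Hba-x, at 481 against 33.6, and Hbb-bh1, at 138 against 2.03, were higher in neural tube.

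Neural crest markers went in both directions and foregut markers past the rule were higher in pancreas. Of 12 neural crest and Schwann markers 2 were higher in neural tube and 3 in pancreas. Fabp7 was at 183 FPKM against 14.3 and Ngfr at 13.2 against 2.55, while Pmp22 was at 3.14 against 36.4 and S100b at 0.0259 against 6.25. Their median of -0.64 (percentile 18.5) turned to 1.16 with a filter of 10 FPKM. Of 16 other foregut and mesothelial markers 6 were higher in pancreas (median -3.37, percentile 0), with Upk3b at 28.8 against 0.413, Afp at 19.1 against 0.0201, Vil1 at 10.1 against 0.0684 and Wt1 at 14.9 against 1.01. The 5 sex-linked genes had a median of 0.55 (percentile 83.0) and 0 past the rule, with Xist at 23.4 in neural tube and 53.4 in pancreas and Eif2s3y at 10.7 and 4.496.

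Immediate early and stress genes, which dissociation can induce, moved in both directions. Of 20 genes 3 were higher in neural tube and 2 in pancreas. Jund was at 105 FPKM against 9.86 and the heat shock gene Hspa1a at 6.26 against 0.579, while Gadd45b was at 0.807 against 12.6 and Hspb1 at 2.19 against 23.0. Their median of -0.51 (percentile 11.965) turned to 0.09 with rescaling to equal totals. Of 20 housekeeping genes 11 were similar, beside 68.4% of all genes at 5 FPKM or more in both samples. Another 3 were higher in pancreas, including B2m at 116 against 9.39 and Gusb at 47.1 against 5.48. Polr2a at 76.4 against 26.8 and Tubb5 at 1273 against 428 were higher in neural tube by less than the rule. The housekeeping median of -0.38 (percentile 47.6) turned to 0.25 with rescaling to equal totals.

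The ribosomal protein and respiratory chain lists had medians below 0, with few members past the rule. Of 80 ribosomal protein genes 14 were higher in pancreas, 0 in neural tube and 27 similar (median -1.33, percentile 0, and -0.71 with rescaling to equal totals). For the 51 members with a transcript length and GC value the median moved from -1.41 to -0.84 with the trend on both removed. Rpl22l1 was at 60.8 FPKM against 1041 and Rps27 at 4.19 against 118, while Rpl34 was at 38.9 against 11.2, which did not pass the rule, and Rpl36 was similar at 1474 and 785. Of 78 nuclear genes of the mitochondrial respiratory chain 4 were higher in pancreas and 36 similar (median -0.90, percentile 0.04, and -0.29 with rescaling to equal totals), with Cox7a1 at 2.65 against 51.3 and Ndufs5 at 4.90 against 47.9. Atp5d was at 215 against 92.5 and Uqcrq at 209 against 93.1, differences below the rule. Leaving out small RNA genes and unnamed models, the highest genes of the neural tube sample were Rpl41 at 4549 FPKM, Rps28 at 3080, the tubulin gene Tuba1a at 2977 and Eef1a1 at 2862. Those of pancreas were Ctrb1, Hba-a1, Beta-s and Amy2b.

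Histone and small RNA genes went in both directions. Of 67 replication-dependent histone genes 17 were higher in neural tube and 4 in pancreas (median 1.17, percentile 100). Hist1h2ap at 19.4 FPKM and Hist2h2aa2 at 16.4 were listed at 0 in pancreas, whereas Hist1h1c was at 2.13 against 57.9 and Hist1h2bc at 3.09 against 53.9. Many histone genes are near-identical copies, so their separate values are uncertain. Of 726 small RNA genes 238 reached 1 FPKM, 59 were higher in neural tube and 94 in pancreas (median -1.03, percentile 0, and 0.00 without a filter). Snord42a at 1533 and Mir762 at 1462 FPKM in neural tube were listed at 0 in pancreas, and Snord99 at 2268 and Snord49a at 1759 in pancreas were listed at 0 in neural tube. FPKM values of transcripts this short are uncertain.

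**Figure D3:**
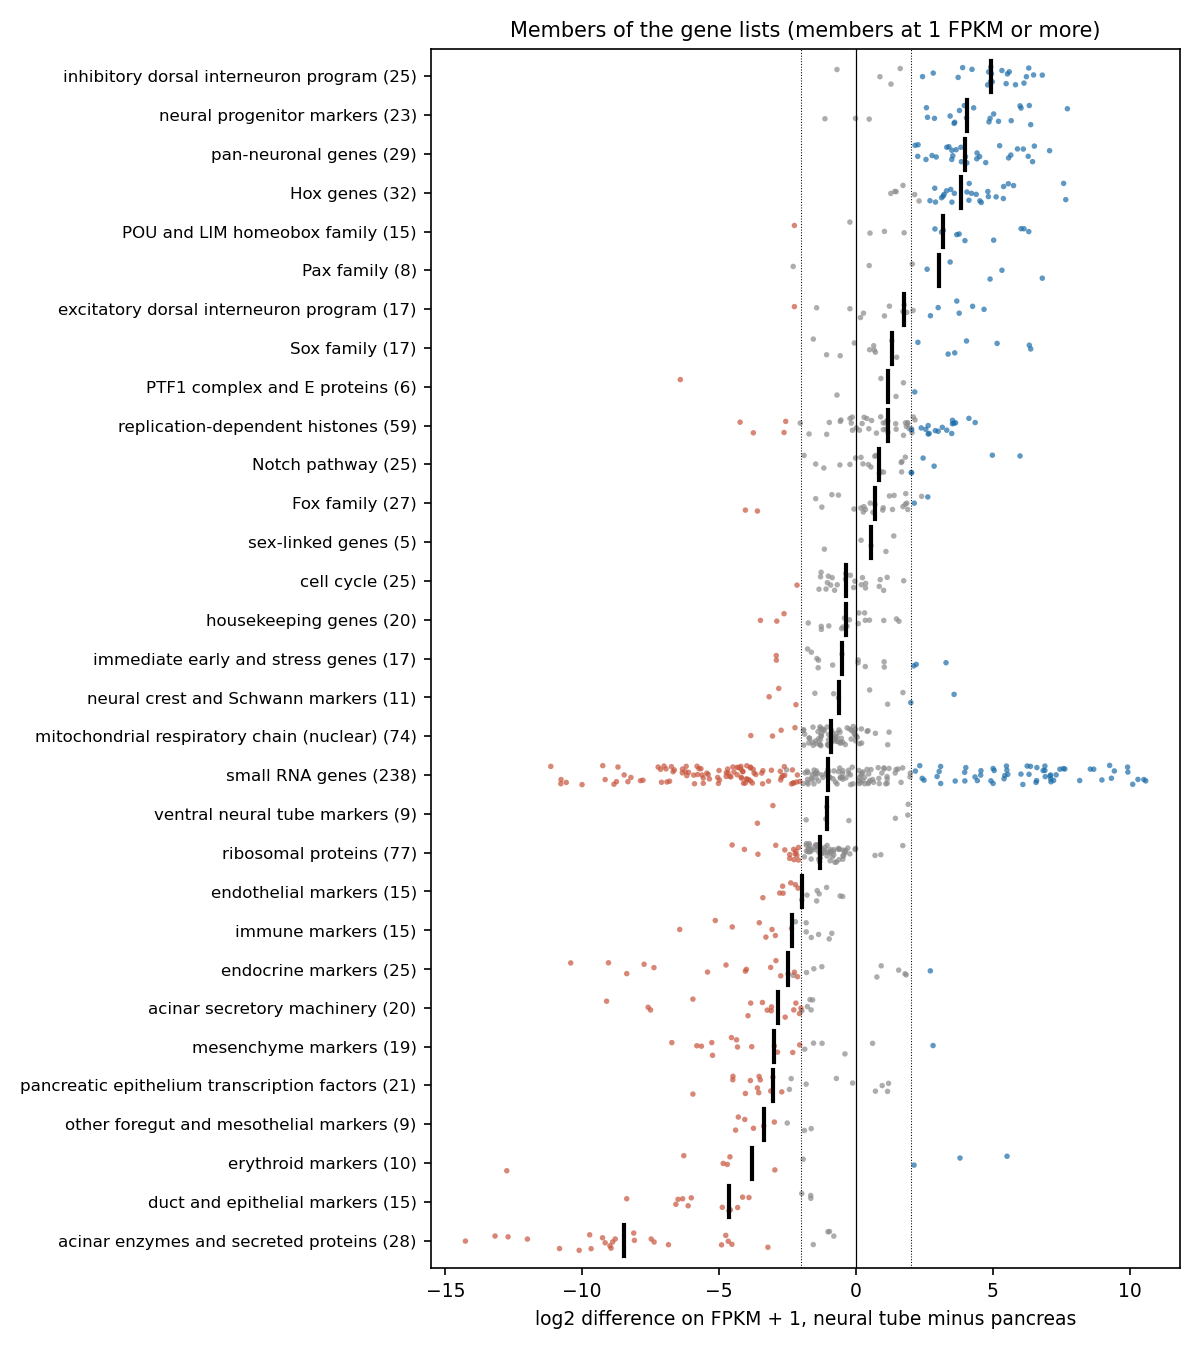
Each point is a list member at 1 FPKM or more in either sample, placed by its log2 difference on FPKM + 1, neural tube minus pancreas, with the number of members in brackets; blue and red mark genes past the rule of size, dotted lines mark 2 and -2, and black bars mark medians. Medians run from -8.46 for acinar enzymes to 4.92 for the inhibitory dorsal interneuron genes; under other settings those of the ventral, cell cycle, housekeeping, immediate early, and neural crest and Schwann lists change sign, and that of small RNA genes becomes 0.00.

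Differences varied with gene length and base composition. Across 9279 genes, Spearman's rho of the difference was 0.25 with transcript length and 0.30 with GC content. With that trend removed, 614 of the 924 neural tube calls that had both properties stayed past the rule, as did 867 of 1040 pancreas calls, and 0 in either group changed sign.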

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

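Genes higher in neural tube and in pancreas, 1106 and 1278 as reported, were 512 and 600 with a pseudocount of 5 FPKM, 2494 and 2690 at 2 times, and 546 and 653 at 8 times, by construction of those settings. Genes higher in neural tube were 1869 with rescaling without the most abundant genes and 2115 with rescaling to equal totals. Those higher in pancreas rose to 1593 and fell to 1139, respectively. Both settings raise values over the fixed 5 FPKM floor and shift the ratio of the samples, by 1.24 and 1.54 times. Their separate parts were not tested. Neural tube calls were 660 with the length and GC correction, which was chosen after seeing the data and drops genes without annotation. Similar genes were 16542 without a filter, which admits genes near 0 in both samples. The count of the 31 lists outside the central 95% of random lists was 25 and ranged from 22 to 25. Several lists share members, such as Pax2, Sox2 and Lhx1, so these are not 31 separate results. A sign change counted as a reversal where both values were at least 1.5 times (0.58 in log2) from 0. By that measure the neural crest and Schwann median reversed to 1.16 with a filter of 10 FPKM. Of that list only Ednrb, Mbp, Pmp22, Fabp7 and Ngfr reached 10 FPKM in either sample. They went in both directions, and 1.16 is the difference of Ednrb, the middle member. Of the other list medians over all alternatives, 306 stayed within 1.5 times with their sign and 118 moved by more or changed sign. Sign changes numbered 8, the reversal and a median of 0.00 included. For named genes 1676 values stayed and 558 moved, with 32 sign changes, of which 0 met the measure of reversal. Handling of repeated symbols was not run because 0 symbols were repeated. Leaving out libraries was not run because the table gives 1 value per tissue. No paired analysis was possible because each tissue had a single pooled value. Depth limits the low values, since 3 fragments on a 1 kb transcript correspond to about 0.131 FPKM in neural tube and 0.0720 in pancreas.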

Other observations

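The gene lists in the first 2 paragraphs were chosen after seeing the data, as were all the tests of explanations that follow. Because these lists were picked with the same values in view, their percentiles are descriptions only and give no support for a shift. Some of their members were also in the lists fixed before. RNA of some axon guidance genes and of some GABA, glycine and glutamate receptor subunits was higher in the sorted neural tube cells. Of 72 axon guidance ligands and receptors 21 were higher in neural tube and 3 in pancreas (median 1.17, percentile 100). Robo3 was at 201 FPKM against 0.0260 and the netrin receptor Dcc at 54.9 against 0.109, while Epha1 at 0.363 against 7.95 and Sema3c at 1.20 against 10.99 were higher in pancreas. Of 22 GABA and glycine receptor subunits 5 were higher in neural tube (median 1.93, percentile 99.98), among them Glra1 at 9.82 against 0.0160. The median is that of the 10 subunits at 1 FPKM or more in either sample, and at its weakest was 0.11 over the alternatives. Gabra4 was the 1 subunit higher in pancreas, at 10.1 against 0.127. Of 26 glutamate receptor subunits 4 were higher in neural tube and 0 in pancreas (median 1.59, percentile 100), with Grik3 at 32.1 against 0.681 and Grik2 at 17.2 against 0.339.

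Collagen, keratin, claudin, serpin and metalloproteinase genes past the rule were mostly higher in the whole pancreas. Of 22 collagen genes 11 were higher there (median -2.73, percentile 0), including Col6a2 at 89.8 FPKM against 1.36, while Col18a1 was similar at 37.7 and 22.4. Col1a1, Col1a2, Col3a1, Col5a1 and Col6a1, among those called, were in the mesenchyme list already. Of 47 keratins 4 were higher in pancreas (median -1.95, percentile 0), with Krt8 at 232 against 2.60. The keratins called, Krt7, Krt8, Krt18 and Krt19, were all in the duct and epithelial list already. The median is that of the 11 keratins at 1 FPKM or more in either sample, and at its weakest was -0.03 over the alternatives. Of 26 claudins 6 were higher in pancreas (median -1.43, percentile 0.1), with Cldn10 at 209 against 0.773, and Cldn12 was similar at 10.1 and 7.70. Among those called, Cldn3, Cldn4 and Cldn7 were in the duct and epithelial list already. Of 61 serpins 10 were higher in pancreas (median -2.48, percentile 0), with Serpini2 at 324 and listed at 0 in neural tube. Only 18 serpins reached 1 FPKM in either sample and gave that median, which at its weakest was -0.09 over the alternatives. Of 27 matrix metalloproteinases and inhibitors 3 were higher in pancreas and 1, Mmp24 at 13.0 against 0.269, in neural tube (median -1.13, percentile 1.43). That median is of the 13 members at 1 FPKM or more in either sample, and at its weakest was -0.06 over the alternatives.

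Embryonic globins made up 60.2% of the FPKM of 8 globin genes in the sorted neural tube cells and 0.397% in pancreas. Reads shared between globin copies would give alike shares, and the shares differed by 151.8 times, which argues against that explanation. RNA or cells of the red lineage carried through the GFP sort may have contributed: summed Alas2 and Slc4a1 per globin FPKM was 0.916 times that in pancreas, where a globin signal without red cells could have given another ratio. The sum hides unequal members, with Alas2 at 2.08 FPKM in neural tube and 87.8 in pancreas and Slc4a1 at 2.59 and 12.7. The difference of stage between E12.5 and E15.5 was not tested and stays open.

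The ribosomal protein list had a median of -1.33. A single scaling factor between the samples would move all genes alike. The list median lay at -1.36 relative to the median of all genes (bootstrap range -1.48 to -1.08), which argues against such a factor as the cause. Bootstrap ranges here and below resample the members of a list and do not measure variation between samples. With the length and GC trend fitted on other genes and removed, the median of 51 members moved from -1.41 to -0.84. That check is void as a decision, because only 66.2% of the 77 members had both properties, so the trend and a difference of tissue, stage or library preparation cannot be told apart.

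Replication-dependent histones had a median of 1.17 toward neural tube, and more cells in S phase could be a source. The median difference of 11 G1/S and S-phase genes was 0.19 (bootstrap range -0.78 to 0.35) against 1.17 for the histones (0.90 to 1.89). That argues against S phase as the whole cause only if these genes shift as much as histones do, which was not tested. Splitting of reads between near-identical copies leaves the sum of the list unaltered if reads that match several copies were kept, which is not known. That sum was 437 FPKM in neural tube and 216 in pancreas, a log2 ratio of 1.02. Single members weighed heavily in it in both directions, with Hist3h2ba at 102 FPKM against 7.99 and Hist1h1c at 2.13 against 57.9. The sum therefore does not decide on read splitting. More RNA without a poly(A) tail in the neural tube libraries stays open: 5 such RNAs, Rmrp, Rpph1, Terc, Rn45s and Rn4.5s, picked because they had been seen to be higher, had a median of 1.73, but the small RNA list fixed beforehand had a median of -1.03, so the 2 sets go opposite ways and decide nothing. Differences of tissue and stage were not tested.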
